A study of Mus musculus with 18 samples.

How the data were processed

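Libraries were made from 9000 to 20000 YFP+ thyroid cells sorted into TRIzol, by a low-input messenger RNA protocol with 14 cycles of PCR, and sequenced as paired reads of 100 bp. The aligner, the quantification tool, the genome build and the annotation behind the deposited table are not given in the sources used here, so no coordinates are printed. The table has 23652 entries named by gene symbol and 18 columns. The deposited values were treated as TPM, a transcript abundance scaled to a fixed total, because each column sums to 1000000. The table is called normalized counts, and such a total does not settle the unit by itself. No counts or read totals were used here. The depth is therefore unknown, and no counting interval or detection limit is given. The 26 entries whose names had been turned into dates were left out (at most 0.0455% of a library's TPM), which left 23626, of which 23498 matched a symbol of the mouse reference annotation; no 2 columns were identical. The reference was used for names and transcript lengths alone.

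Groups were taken from the genotype labels: BrafV600E (n = 4), BrafV600E with Tert-123C>T (n = 7), BrafV600E with K5-Tert (n = 4) and 3 single pools without Braf mutation. Libraries are numbered within each group in the order of the series, and the numbers pair nothing. The sex of the mice, the number of mice per pool and the batches are not in the labels. The numbers in the sample names of the Braf and Tert-123 tumours interleave, while those of the K5-Tert tumours are all higher. Whether this marks separate cohorts or runs is not stated, so any such difference cannot be told apart from K5-Tert. Genes were kept when they reached 10 TPM in at least 4 libraries, and were fitted as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no robust step. The 3 tumour groups were fitted together for the tumour comparisons (12 residual degrees of freedom), and the Braf mutation was fitted beside the Tert allele over all 18 libraries for the comparison with tissue lacking it (14 residual degrees of freedom). Tests were two-sided, p was adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p under 0.05. Tert was also compared by exact permutation tests of log2(TPM + 1) between groups.

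The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule names Tert and Braf always, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50 TPM, and up to 4 members with the smallest p of each list that was called or had members past the threshold; where fewer than 3 genes pass in a direction, it adds those with the smallest p up to 5. A few genes that the rule names are not reported here; they stay in every fit, list and count of genes, but not in the counts over named genes. The 39 lists cover thyroid differentiation, MAPK output, PI3K and mTOR, telomere maintenance, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, cell cycle, p53, stress, unfolded protein response, NF-kB, interferon, cytokines and their receptors, TGF-beta, YAP, Wnt, matrix, adhesion, epithelial-mesenchymal transition and markers of other cells the sort could hold. The 29 lists with at least 4 tested members in a comparison were tested with camera (limma) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. The mean log2 level of each list was compared between tumour groups by exact permutation tests, in which 0 lists passed after adjustment, and 1 list alone could not have. For the pools, median ratios of lists were set against 10000 random lists of equal size. The overlap of the Tert effects was set against 100 simulations with shared controls and no true effect.

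The methods were tested on simulated data built from these libraries. limma recovered 33% of genes changed by 1 on the log2 scale and 92% of those changed by 2 in the comparison of K5-Tert with Braf tumours. A median of 1 unchanged gene was called, at most 14, with some called in 12 of 20 simulations. The most was 58 for Tert-123 against Braf tumours and 51 for Braf tumours against tissue lacking the mutation. Residuals were shuffled across all libraries, so a spread or shift particular to K5-Tert tumours is not simulated, and false calls from it are not measured. In the same simulations camera with the preset correlation called a median of 7 of 29 unchanged lists, and with the estimated correlation and by fry 0. Alternatives were a pseudocount of 0.5 or 5, no filter, a filter at 50 TPM, factors of the TMM type (30% of ratios and 5% of levels trimmed), quantile normalization, library weights, Xist as a covariate, fits of only the groups compared, and leaving out each library. Chosen after the data were seen were TPM rescaled without Rpph1, removal of each library's mean and trend against transcript length (for K5-Tert against Braf tumours also of the slope alone and of the mean alone), fits without libraries that stood apart, and fits split by Xist level. Other groupings of the same samples were refitted, at most 100 per comparison.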

Results

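Messenger RNA was sequenced from 18 libraries of sorted mouse thyroid cells taken at 20 weeks. The labels describe every library as thyrocytes sorted for a yellow fluorescent protein (YFP). 15 libraries came from tumours carrying BrafV600E, a mutation that keeps the kinase Braf active. 4 of these carried the Braf mutation alone (Braf tumours), 7 also carried the Tert promoter change Tert-123C>T (Tert-123 tumours), and 4 also carried K5-Tert, a transgene that drives Tert from a keratin 5 promoter (K5-Tert tumours). The other 3 libraries were single pools without the Braf mutation, from K5-Tert, Tert-123C>T and wild-type mice. Tert encodes the catalytic subunit of telomerase, and the series asks what a higher level of it does in Braf-driven thyroid tumours. Levels are given as transcript abundance in TPM, the unit the values were taken to have, and the read depth is unknown. The noncoding RNA Rpph1, the RNA part of ribonuclease P, took 43.7% to 68.8% of the TPM in a library, and 10958 to 15045 genes reached 1 TPM. The labels do not say that each library is a separate animal, so every p-value measures the spread between these samples.

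Tert was measured first, because it is the gene the alleles act on. Its level was 4.59 ± 0.603 TPM (SD, n = 4) in Braf tumours, 5.18 ± 1.34 TPM (n = 7) in Tert-123 tumours and 39.3 ± 29.4 TPM (n = 4) in K5-Tert tumours. The 4 K5-Tert tumours held 73.9, 11.2, 19.0 and 53.4 TPM, and all 4 lay above every Braf tumour. K5-Tert tumours differed from Braf tumours by 2.50 on the log2 scale (two-sided exact permutation test, p = 0.02857, the smallest that 70 arrangements allow) and from Tert-123 tumours by 2.39 (exact p = 0.00303, 330 arrangements). Tert-123 and Braf tumours differed by 0.12 on the log2 scale, less than the spread between tumours (exact p = 0.5848). In the pools Tert was 125 TPM with K5-Tert, 8.79 TPM with Tert-123C>T and 2.15 TPM in the wild type. The Tert-123C>T pool also held transcripts of other cells, such as Cd3g of T cells at 96.1 TPM. Its Tert level therefore cannot be assigned to thyrocytes. Braf itself was 8.11 ± 1.49 TPM (n = 4), 7.87 ± 1.08 TPM (n = 7) and 4.41 ± 2.11 TPM (n = 4) in Braf, Tert-123 and K5-Tert tumours, below the level at which genes were tested.

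**Figure D1:**
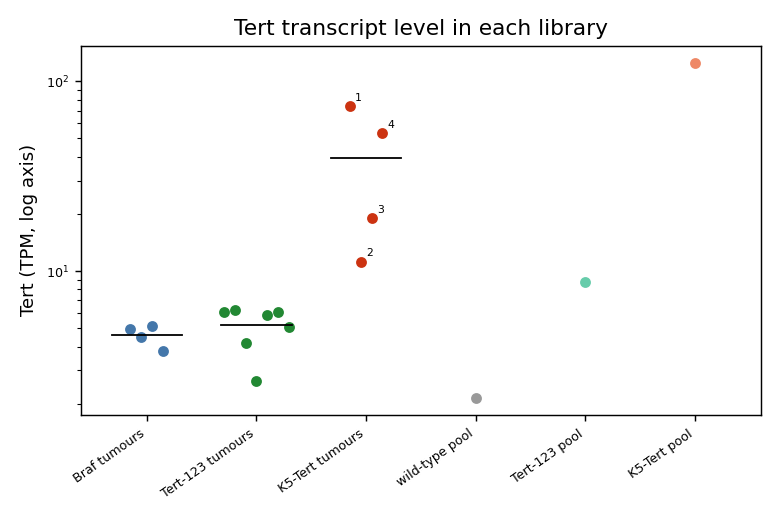
Tert level in TPM on a log axis in each of the 18 libraries, by group. Each point is 1 library and lines mark the group means; all 4 K5-Tert tumours, at 11.2 to 73.9 TPM, lie above every Braf tumour.

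The comparison of Tert-123 with Braf tumours asks what the promoter change adds to the Braf mutation. No gene passed the test, so the genes with the smallest p are given by level only. Cmc1, a mitochondrial protein, was at 5.74 ± 1.53 TPM in Braf tumours (n = 4) and 12.6 ± 3.53 TPM in Tert-123 tumours (n = 7), where 7 of 7 lay above every Braf tumour. It was picked by its small p in these same tumours, so that separation is no support. Apobec3, a cytidine deaminase that restricts retroviruses, was at 13.3 ± 1.92 TPM and 32.9 ± 10.8 TPM, and Cracr2a, a calcium-binding protein, at 15.4 ± 3.50 TPM and 8.75 ± 1.63 TPM. The complement genes C1qb (37.8 ± 5.85 TPM and 92.8 ± 64.4 TPM) and C1qa (45.2 ± 12.2 TPM and 91.8 ± 61.6 TPM) of the macrophage list did not pass either. limma called 0 of 7498 genes (smallest adjusted p = 0.9997), and 50 had an unadjusted p under 0.05, where chance alone gives 375. The set test camera with its preset correlation called 7 of 29 lists, in none of which a member passed: macrophage, endothelial, oxidative phosphorylation, stress, unfolded protein response and ribosomal protein genes higher, and basal keratinocyte genes lower. With an estimated correlation it called 0 of the lists.

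The comparison of K5-Tert with Braf tumours asks what a transgene that gives high Tert adds. Il1b, an inflammatory cytokine, rose from 6.79 ± 2.42 TPM (SD, n = 4) to 173 ± 193 TPM (n = 4), a log2 fold change of 3.89 (adjusted p = 0.002332). The immediate-early genes Fosb (7.56 ± 3.64 TPM to 83.0 ± 50.6 TPM, log2 3.21), Nr4a1 (4.69 ± 1.35 TPM to 41.2 ± 23.6 TPM, log2 2.74) and Atf3 (17.97 ± 10.4 TPM to 117 ± 73.2 TPM, log2 2.62) rose with it. So did Cxcl2, which attracts neutrophils (log2 2.54), and Cd14, a receptor for bacterial lipopolysaccharide (17.7 ± 5.97 TPM to 148 ± 202 TPM, log2 2.18). Tle2, a transcriptional corepressor, fell from 79.1 ± 6.21 TPM to 17.8 ± 9.56 TPM (log2 -2.20, adjusted p = 0.0003687). The imprinted noncoding RNA Meg3 fell from 144 ± 67.7 TPM to 15.8 ± 11.02 TPM (log2 -3.19). Each of these genes lay outside the range of the Braf tumours in 4 of 4 K5-Tert tumours and passed under 5 of 5 scalings of the values. Chance gives 2.86% of genes with groups of 4 and 4 that do not overlap. These genes were picked by their changes in the same tumours, so that share does not apply to them and the separation is no further support.

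**Figure D2:**
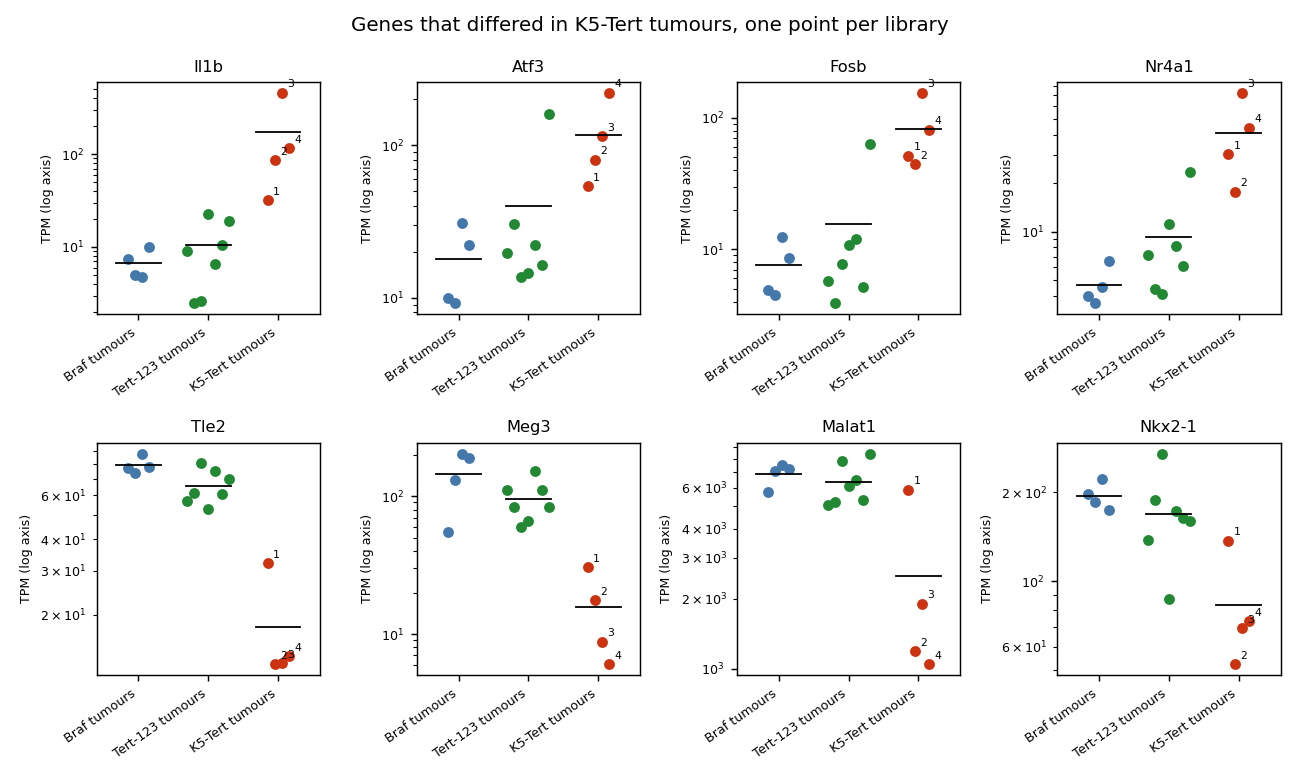
Levels in TPM on a log axis of 8 genes in Braf, Tert-123 and K5-Tert tumours. Points are libraries, lines are group means, and K5-Tert points carry the library number; all 4 K5-Tert tumours lie above the Braf tumours for Il1b, Atf3, Fosb and Nr4a1 and below them for Tle2, Meg3 and Nkx2-1 (Nkx2-1 did not pass after TMM-type rescaling), while for Malat1 tumour 1 is at 5902 TPM and the other 3 at 1050 to 1908 TPM.

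Among the lists fixed in advance, the stress and immediate-early list had 8 of 22 members higher, 0 lower and 14 not past the test (8 and 0 adjusted over the list alone). Among them were Fos, Dusp1 (26.2 ± 12.4 TPM to 76.2 ± 35.2 TPM) and the heat shock gene Hspa1a (32.6 ± 5.50 TPM to 79.5 ± 27.6 TPM). Of 44 cytosolic ribosomal protein genes 9 rose and 0 fell (9 and 0 adjusted over the list alone). Rps7 went from 321 ± 64.3 TPM to 790 ± 190 TPM and Rpl3 from 284 ± 36.3 TPM to 501 ± 40.1 TPM. Relative to the median of all genes these lists stood 1.02 and 0.92 higher on the log2 scale, each with adjusted p = 0.138 with an estimated correlation. Of 14 cytokine genes 2 rose (Il1b and Cxcl2). Of 14 macrophage markers 1 rose (Cd14), and of 4 pericyte and smooth muscle markers 2 rose (Acta2 and Tagln). In these 3 lists 0 fell, and the counts adjusted over the list alone were the same. The thyroid list had 0 of 13 members higher and 5 lower (5 adjusted over the list alone). The thyroid transcription factor Nkx2-1 went from 195 ± 20.5 TPM to 83.0 ± 37.3 TPM, and the factors Hhex from 149 ± 21.4 TPM to 60.3 ± 28.0 TPM and Glis3 from 43.1 ± 7.07 TPM to 19.2 ± 9.06 TPM. The median of this list stood at -0.03 against all genes. Of 22 MAPK output genes 1 rose and 6 fell (7 adjusted over the list alone), including the ETS factor Etv4 (43.5 ± 9.10 TPM to 20.6 ± 7.38 TPM). Of 18 telomere genes Tert rose and 6 fell (7 adjusted over the list alone), including the telomere-binding factors Terf1 (10.9 ± 1.20 TPM to 4.91 ± 2.09 TPM) and Terf2 (10.4 ± 1.003 TPM to 4.63 ± 2.42 TPM). Of 24 PI3K and mTOR genes 7 fell and 1 rose, and of 24 ribosome biogenesis genes 6 fell and 0 rose. No member of the oxidative phosphorylation (45 genes), class II antigen presentation (6), endothelial (6), interferon (12), airway (4) or cell cycle (10) lists passed as deposited. Each of the receptor, NF-kB, TGF-beta target, unfolded protein response, epithelial-mesenchymal and fibroblast lists had 1 or 2 members higher and 0 lower. Some of these are genes already counted above. The unfolded protein response member is Atf3 of the stress list, the epithelial-mesenchymal member is Tagln, and the NF-kB members include Cxcl2. The adhesion list (4), basal keratinocyte list (2), and matrix, glycolysis, p53 and Wnt lists (1 each) had members lower only as deposited (1, 2, 0, 0, 0 and 3 adjusted over the list alone). YAP targets had 1 higher and 3 lower.

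In limma, 44 genes were higher and 1641 lower of 7498 tested, with 3038 at an unadjusted p under 0.05. The median log2 fold change of all genes was -0.48, and 3 of the 4 K5-Tert tumours (2, 3 and 4) also had Malat1 at 1191, 1908 and 1050 TPM against 5762 to 7496 TPM in Braf tumours. Rescaling by TMM-type factors brought that median to 0.07, and the counts to 468 higher and 373 lower. With each library's mean and its trend against transcript length both removed they were 331 higher and 399 lower. With the length slope alone removed they were 25 and 1358, and with the mean alone removed 392 and 632. The fold changes fell with transcript length (rho = -0.418). Levels relative to the mean of the tumours fell with it in K5-Tert tumours 2, 3 and 4 (rho -0.54, -0.25 and -0.42), while they rose in tumour 1 (0.27) and in the Braf tumours (0.16 to 0.37). Among Tert-123 tumours they fell in tumour 7 (-0.17) and rose in the others (0.07 to 0.32). RNA quality is not in the labels, and it remains a doubt for the list changes above. Under all 5 scalings 35 of the higher and 249 of the lower genes kept their call. The lists were counted again under 4 settings, in the order TMM-type rescaling, quantile normalization, length trend and mean removed, and rescaling without Rpph1, the last of which tests more members. Members lower were 1, 3, 2 and 5 in the thyroid list, 0, 0, 2 and 7 in the telomere list and 0, 1, 2 and 5 in the MAPK list. They were 0, 0, 0 and 7 in the PI3K and mTOR list and 0, 1, 2 and 7 in the ribosome biogenesis list. Ribosomal protein genes higher were 34, 8, 24 and 23, and stress genes 14, 10, 14 and 12. The ribosomal protein median against all genes was 0.94, 0.30, 0.62 and 0.99, and that of the stress list 1.03, 0.64, 0.97 and 1.08. Oxidative phosphorylation genes, of which 0 passed as deposited, had 14, 2, 9 and 5 higher and 0 lower, and interferon genes 1, 1, 0 and 0 higher. Adhesion genes lower were 0, 0, 0 and 1, and Wnt genes 0 in each. Members higher were 2, 3, 4 and 2 in the receptor list, 6, 5, 3 and 5 in the NF-kB list and 4, 2, 2 and 2 in the TGF-beta list. They were 6, 2, 5 and 1 in the unfolded protein response, 1 in each in the epithelial-mesenchymal and 2, 1, 1 and 1 in the fibroblast list, with 0 lower in these 6 lists. Glycolysis genes turned to 4, 2, 1 and 0 higher with 0 lower. Matrix genes had 2, 1, 2 and 0 higher and p53 genes 1, 1, 0 and 1, and both had 0, 0, 0 and 1 lower. Relative to all genes by TMM-type rescaling, Nkx2-1 stood at -0.75 (adjusted p = 0.08769) and Hhex at -0.82 (adjusted p = 0.0505). Etv4 stood at -0.53 (adjusted p = 0.09114) and Terf2 at -0.65 (adjusted p = 0.06306). None of these 4 passed, while Il1b stood at 4.43 and Tle2 at -1.66, both past it. camera with the preset correlation called 18 of 29 lists, all higher than other genes; with an estimated correlation their adjusted p ran from 0.1381 to 0.4914, and with it and by fry the number called was 0. Without K5-Tert tumours 2 and 4 the counts were 3 higher and 15 lower, and without 2, 3 and 4 they were 0 and 2. The latter leaves 1 tumour, assumed to vary like the others. Without 2 and 4, 5 of the 8 genes named first did not pass: Il1b at 4.03 (adjusted p = 0.05769), Fosb at 3.50 (0.0611), Cxcl2 at 2.78 (0.104), Cd14 at 2.64 (0.1459) and Atf3 at 2.24 (0.1938). Nr4a1, Tle2 and Meg3 passed. Of these 5 folds 4 were larger than with all tumours and that of Atf3 was smaller, so with 2 K5-Tert tumours left the lost calls do not show that the rises rest on tumours 2 and 4. Xist, expressed from the inactive X chromosome of females, reached 10 TPM in 4 of 4 Braf, 4 of 7 Tert-123 and 1 of 4 K5-Tert tumours, so transcripts linked to sex run partly with this comparison; with Xist as a covariate 12 genes were higher and 225 lower.

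**Figure D3:**
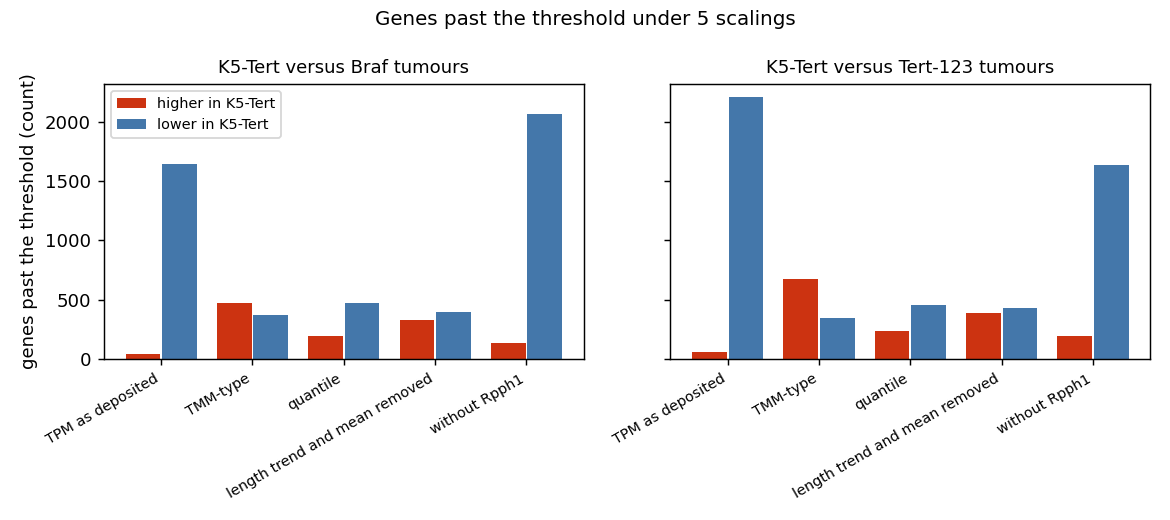
Number of genes called higher and lower in K5-Tert tumours, against Braf and against Tert-123 tumours, under 5 scalings of the TPM values. Bars start at 0; against Braf tumours the lower calls go from 1641 as deposited to 373 after TMM-type rescaling, and the higher calls from 44 to 468.

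The comparison of K5-Tert with Tert-123 tumours asks whether the transgene and the promoter change differ. Il1b was 10.4 ± 7.79 TPM in Tert-123 tumours (n = 7) and 173 ± 193 TPM in K5-Tert tumours (n = 4), higher by 3.61 on the log2 scale (adjusted p = 0.001379) and above every Tert-123 tumour in 4 of 4. Fosb (log2 2.78), Cxcl2 (2.67), Cd14 (2.15) and Nr4a1 (2.07) were higher too, but above every Tert-123 tumour in only 2 of 4 for Fosb and 3 of 4 for the other 3. Higher as well was the ribosomal protein gene Rps21 (374 ± 111 TPM and 738 ± 220 TPM). Meg3 (log2 -2.69) and Tle2 (-1.92) were lower, each below every Tert-123 tumour in 4 of 4. The genes named here were picked by their changes in these tumours, so such separation is no further support. The nuclear noncoding RNA Neat1 was at 91.7 ± 22.9 TPM and 28.8 ± 21.4 TPM (log2 -1.84), and Malat1 at 6356 ± 1325 TPM and 2513 ± 2291 TPM (log2 -1.69), below the range in 3 of 4. Of the lists, 15 of 44 ribosomal protein genes and 6 of 22 stress genes were higher and none lower, while 5 of 13 thyroid, 7 of 18 telomere and 10 of 24 PI3K and mTOR genes were lower (adjusted over the list alone, 15, 6, 6, 9 and 15). After TMM-type rescaling these counts were 39, 16, 1, 1 and 0, and after quantile normalization 17, 10, 3, 0 and 1. They were 28, 14, 0, 2 and 0 with the length trend and mean removed. Without Rpph1, with more members tested, they were 32, 14, 5, 8 and 4. The stress score of Tert-123 tumour 7 was 7.01, above every K5-Tert tumour (5.84 to 6.90). limma called 57 genes higher and 2210 lower of 7498, with 3424 at an unadjusted p under 0.05; 35 of the higher and 1485 of the lower genes were also called against Braf tumours. The all-gene median was -0.48 and the counts after TMM-type rescaling were 675 and 347. Without K5-Tert tumours 2 and 4 they were 3 and 14, and 0 of the 57 higher and 14 of the 2210 lower genes kept their call. Il1b then stood at 3.75 (adjusted p = 0.0646), Fosb at 3.06, Cxcl2 at 2.91, Cd14 at 2.62, Nr4a1 at 2.43 and Meg3 at -2.38, none past the threshold, and Rps21 at 0.90 (0.98 with all tumours) did not pass either, while Tle2 passed (-1.62). camera called 19 lists, the smallest adjusted p = 0.1505 with an estimated correlation.

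The comparison of all 11 Tert-altered tumours with the Braf tumours takes the mean of the Tert-123 and K5-Tert groups at equal weight. The 4 K5-Tert tumours thus count as much as the 7 Tert-123 tumours. Tle2 fell (log2 -1.24) and so did Cracr2a, with 15.4 ± 3.50 TPM in Braf tumours (n = 4) against 8.75 ± 1.63 TPM (n = 7) and 3.01 ± 1.08 TPM (n = 4) in Tert-123 and K5-Tert tumours (log2 -1.40, adjusted p = 0.04972 for both genes). Tert was at log2 1.31 and did not pass (adjusted p = 0.1693), nor did Csrnp1, an immediate-early transcription factor (1.09, adjusted p = 0.09227), Nr4a1 (1.71), Il1b (2.08) or Meg3 (-1.85). limma called 0 genes higher and 2 lower, and 1251 had an unadjusted p under 0.05. Both calls were lost after TMM-type rescaling. No gene was called without any 1 of Braf tumours 2, 3 and 4, Tert-123 tumours 1, 2, 3, 4, 6 and 7 or K5-Tert tumours 2 and 4. There were 5 lower without Braf tumour 1, 8 without Tert-123 tumour 5 and 1 without K5-Tert tumour 3, and 15 higher and 1195 lower without K5-Tert tumour 1. camera called 17 lists, the smallest adjusted p = 0.2453 with an estimated correlation. Whether the alleles share an effect was asked across genes, which are not independent replicates. Their log2 fold changes against the shared Braf tumours had r = 0.481, and 66 of 100 simulations with no true effect but shared controls gave an r as large. With the Braf tumours divided between the comparisons r was 0.170 to 0.303.

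The comparison of Braf tumours with tissue lacking the Braf mutation asks what the mutation does, with the Tert allele fitted beside it. Its fold changes, calls and list counts come from a fit of all 15 tumours with mutant Braf and the 3 pools. The mean levels given beside them are those of the 4 tumours with the Braf mutation alone. Genes of lung surfactant were among the largest rises: Sftpb was at 5464 ± 1649 TPM in Braf tumours (n = 4) against 6.38, 6.89 and 47.8 TPM in the wild-type, Tert-123C>T and K5-Tert pools (n = 1 each; log2 8.31, adjusted p = 1.149e-12), and Sftpd at 1319 ± 84.6 TPM against 0, 0.769 and 8.21 TPM. The secreted proteins Spp1 (2226 ± 489 TPM against 2.10, 9.78 and 21.4 TPM), Lcn2 (1067 ± 268 TPM against 1.68, 0 and 13.8 TPM) and Chil1 and the keratin gene Krt20 also rose. Thyroglobulin, Tg, the precursor of thyroid hormone, fell from 31239.7, 25676 and 30045 TPM in the pools to 143 ± 76.6 TPM (log2 -7.49, adjusted p = 1.022e-11). The iodotyrosine deiodinase Iyd was at 39.8 ± 13.7 TPM against 819, 481 and 1346 TPM. For each of these genes all 15 tumours lay outside the range of the 3 pools, and each passed under 5 of 5 scalings. They were picked by their changes in the same libraries, so the separation is no further support.

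**Figure D4:**
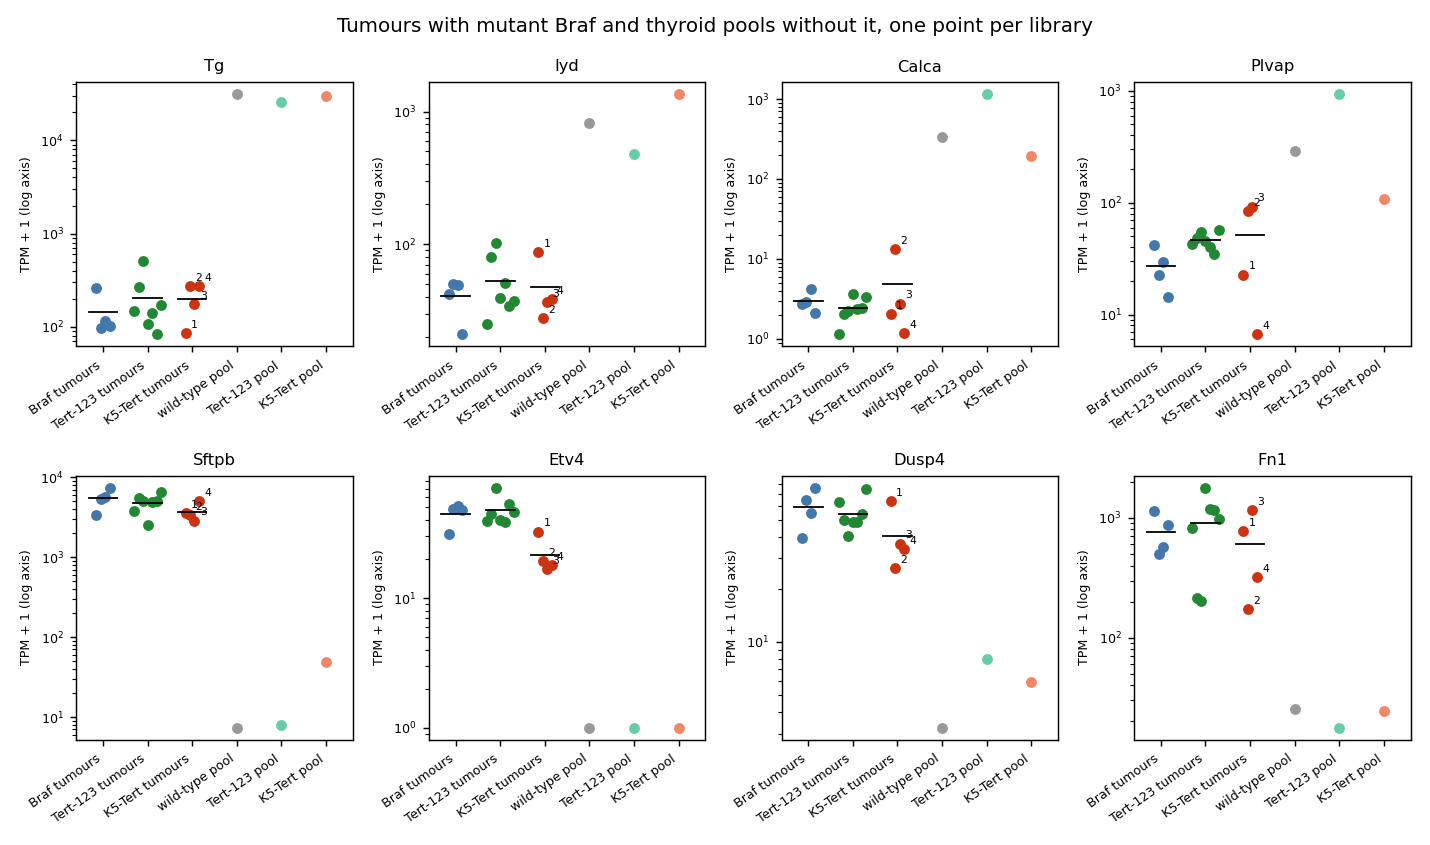
Levels of 8 genes as TPM + 1 on a log axis in the 3 tumour groups and the 3 pools. Points are libraries and lines are group means; Tg is at 25676 to 31239.7 TPM in the pools and Sftpb at 2510 to 7423 TPM in the tumours.

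The MAPK output list had 12 of 22 members higher and 5 lower (13 and 5 adjusted over the list alone). Etv4 was at 43.5 ± 9.10 TPM and listed at 0 in the 3 pools. Dusp4, a phosphatase induced by the pathway, was at 57.8 ± 15.7 TPM against 2.24, 7.04 and 4.87 TPM. Cyclin D1, Ccnd1, was at 198 ± 30.4 TPM against 8.09, 13.5 and 8.93 TPM. Matrix genes had 16 of 30 higher and 4 lower (18 and 4), among them fibronectin, Fn1 (766 ± 293 TPM against 24.3, 16.7 and 23.5 TPM). The epithelial-mesenchymal list had 5 of 11 higher, among them Tgfbi (log2 4.60). Of 14 macrophage markers 9 rose (10 adjusted over the list alone), with Lyz2 at 650 ± 164 TPM against 13.6, 40.3 and 29.1 TPM. Of 15 cytokines 6 rose, of 13 fibroblast markers 4, of 6 class II genes 4 (6 adjusted over the list alone) and of 44 ribosomal protein genes 16 (21), with none falling. Of 16 p53 and senescence genes 4 rose and 5 fell. Cdkn2a, an inhibitor of the cell cycle, was at 31.3 ± 4.21 TPM and listed at 0 in the pools. Among the groups that fell, the thyroid list had 8 of 13 lower and 1 higher (9 and 2 adjusted over the list alone). The stress list had 21 of 22 lower, with Fosb at 7.56 ± 3.64 TPM against 788, 1105 and 981.5 TPM. Its score was 8.33 to 8.94 in the pools and at most 7.01 in a tumour. Handling of the pools before lysis cannot be told apart from the Braf mutation for these genes. The unfolded protein response had 16 of 21 lower and 1 higher, with Hspa5 at 247 ± 57.2 TPM against 615, 761 and 1495.5 TPM. Endothelial markers had 7 of 8 lower (8 adjusted over the list alone), with Plvap at 26.0 ± 11.5 TPM against 290, 929 and 106 TPM. Calcitonin, Calca, made by C cells, was at 1.99 ± 0.872 TPM against 336, 1144 and 191 TPM. All 3 tested C cell markers were lower, as were 2 of 3 parathyroid markers, where Pth rests on 632 TPM in the Tert-123C>T pool. Interferon genes had 4 of 14 lower and oxidative phosphorylation genes 4 of 45, with 0 higher in both. Smaller mixtures were seen for NF-kB (3 higher and 5 lower of 21), PI3K and mTOR (3 and 8 of 25), YAP (4 and 5 of 15) and TGF-beta genes (2 and 5 of 17). The same held for receptor (5 and 3 of 19), glycolysis (3 and 4 of 21), Wnt (2 and 2 of 5), pericyte (2 and 2 of 7) and cell cycle genes (4 and 1 of 10). Telomere genes had 4 of 18 higher and 0 lower, ribosome biogenesis 4 of 24 higher and 1 lower, adhesion 0 of 23 higher and 2 lower, basal keratinocyte 1 of 5 higher and airway 2 of 4 higher. Of the markers of other cells 1 adipocyte gene was tested and fell, and 1 neutrophil gene was tested and rose. The 1 tested B and plasma cell gene did not pass, and no erythroid, skeletal muscle or T and NK cell marker reached the level for testing. The 3 tested transcripts linked to sex did not pass, and no mitochondrially encoded transcript has an entry.

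limma called 1205 genes higher and 786 lower of 7825, with 2847 at an unadjusted p under 0.05. camera called 9 lists higher and 6 lower; with an estimated correlation the number was 0 (adjusted p = 0.2312 for stress, 0.4075 for the thyroid, endothelial and unfolded protein response lists, 0.685 for macrophage and 0.769 for MAPK genes), and fry called 9 higher and 5 lower. TMM-type rescaling moved the all-gene median from 0.07 to 0.12 and gave 1811 higher and 1197 lower. Under the 4 settings in the order above, adhesion genes higher were 5, 4, 5 and 4, class II genes higher 5, 4, 1 and 6, oxidative phosphorylation genes lower 5, 10, 20 and 11 and telomere genes lower 0, 2, 1 and 0. The pools are single libraries whose residual spread is assumed to be that of single tumours, and they differed in other cells: leaving out the wild-type pool gave 764 higher calls, and leaving out the K5-Tert pool gave 1818 higher and 432 lower.

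Against the wild-type pool, at least 4-fold differences among genes reaching 50 TPM were counted without a test. The Tert-123C>T pool had 53 of 1454 genes higher and 6 lower, among them transcripts of salivary and lacrimal glands (Mucl2 at 1563 against 1.34 TPM, Scgb1b27 at 830 TPM and listed at 0), of T cells (Cd3g at 96.1 TPM and listed at 0) and of the parathyroid (Pth at 632 against 26.3 TPM). The median log2 ratio of its T and NK cell markers was 4.53, of its macrophage markers 2.43 and of its thyroid genes -0.71. The K5-Tert pool had 17 of 1731 genes higher and 9 lower, with Tert at 125 against 2.15 TPM and the clock genes Arntl at 50.8 against 4.77 TPM and Dbp at 2.64 against 102 TPM. Its endothelial markers had a median log2 ratio of -1.56 and its stress genes 0.81. The 1731 genes that reached 50 TPM in either pool had a median of 0.51. List members needed only 10 TPM in any library, so that median is over another set of genes.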

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

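Of the tests in this part, the groupings of the samples, and that of a few abundant RNAs, were fixed before their results were seen, although for the abundant RNAs the result without Rpph1 alone was already known and the leaving out of 1 library was added after; those of transcript length, sex, genotype, macrophages, handling, lung cells and scaling were chosen only after.

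The first pattern is that most calls were lower in K5-Tert than in Braf tumours (44 higher, 1641 lower). For transcript length, the length slope was removed and each library's mean kept. Calls were then 25 higher and 1358 lower. Of 1621 lower genes with a length 1179 kept the call, and their median was -0.90, from -1.02. That step leaves the all-gene median at -0.47 and so keeps lower calls by its design. It shows only that the slope by itself is not the whole cause. Whether length also moved the library means cannot be told from it. With slope and mean both removed, calls were 331 higher and 399 lower and 397 genes kept it. Removing the mean alone already gave 392 higher and 632 lower, so most of that drop comes with the mean. Sex is argued against as the whole cause. Between libraries lacking Xist 97.8% of the calls of K5-Tert against Tert-123 tumours were lower. With Xist as a covariate the median of the 1641 genes stayed at -1.02. Their median standard error went from 0.291 to 0.367, as group and Xist run together, so that only 212 kept the call. What moved the library means stays open. The trends of K5-Tert tumours 2, 3 and 4 against length were negative (rho -0.54, -0.25 and -0.42), as was that of Tert-123 tumour 7 (-0.17). Those of K5-Tert tumour 1, the Braf tumours and the other Tert-123 tumours were positive. RNA quality, which the labels do not give, was not tested. A few abundant RNAs taking the TPM stay open, because without the 100 most abundant genes the all-gene median went from -0.48 to -0.23, and leaving out 1 library in turn moved it between -0.30 and -0.17, across the bound of -0.2 set for it; the K5-Tert genotype acting in every library cannot be told apart from a state of tumours 2, 3 and 4, whose lower genes stood at -1.55, -0.87 and -1.43 against the Braf mean; in tumour 1, with the highest Tert, they stood at -0.28, and 1 library cannot decide. Of the 35 groupings of the 8 tumours 2 gave as many calls as the real 1685, the highest other being 2938 with Braf tumour 1 placed among K5-Tert tumours 2, 3 and 4, so chance cannot be excluded and a structure of these tumours is pointed to.

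The second pattern is that Il1b, Cxcl2, Cd14 and immediate-early genes were higher in K5-Tert than in Braf tumours. The YFP gate should remove macrophages, yet the pan-leukocyte gene Ptprc was at 3.29 to 35.1 TPM in K5-Tert tumours. A larger number of macrophages alone is argued against as the cause of the Il1b rise in K5-Tert tumours 1, 2 and 4. Without tumour 3 the other 13 macrophage markers had a median of 0.35 after TMM-type rescaling (quartiles 0.10 and 0.73), while Il1b stood at 3.83. These markers do not speak to neutrophils, of which 1 marker was tested, or to the state of the macrophages. For all 4 tumours and genes macrophages stay open, with a median of 0.34 over those markers as deposited and 0.88 after rescaling, and the most abundant marker, Lyz2, at 650 ± 164 TPM in Braf and 985 ± 1084 TPM in K5-Tert tumours. Handling of the tissue before lysis also cannot be told apart from the genotype. The lowest K5-Tert stress score minus the highest Braf score was -0.027, so the groups overlap. The labels give no batch, but the numbers in the sample names set the K5-Tert tumours apart from the other tumours. The K5-Tert genotype itself remains an open biological explanation.

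The third pattern is surfactant genes in all 15 tumours with mutant Braf, with Sftpb at 2510 to 7423 TPM. Lung cells in the sort, which the YFP gate should also remove, are argued against: Sftpc, a surfactant gene of lung alveoli, was at most 0.308% of Sftpb in a tumour, Scgb1a1 was at most 4.53 TPM and Cldn18 at most 0.754 TPM. The TMM-type factors ran from 0.562 to 1.29, too small a range to account for rises of this size. After that rescaling the smallest of the log2 fold changes of Sftpb, Sftpd and Sftpa1 was 8.37. The size of the factors fixed this outcome, so it is not a separate test of scaling. Of the 11 lung genes looked at, 3 others of type 2 cells were higher in tumours than in the pools: Napsa (377 to 1612 TPM against 50.5 to 105.5 TPM), Slc34a2 (9.72 to 426 TPM against 0.518 to 3.80 TPM) and Lamp3 (2.20 to 156 TPM against 0 to 0.197 TPM). Abca3 was lower (14.5 to 38.7 TPM against 43.7 to 57.2 TPM). Expression by the Braf mutant thyroid cells themselves may account for it, as a hypothesis found and tested on the same data, with the pools as its only controls.

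The other groupings gave these results. For Tert-123 against Braf tumours 100 of 100 groupings gave at least the real count of 0 (highest other 1), as any grouping must, so this says nothing about chance. For K5-Tert against Tert-123 tumours 2 of 100 did, counting the real grouping (real 2267, highest other 3027, with Tert-123 tumours 1 and 2 beside K5-Tert tumours 2 and 4). For Braf tumours against tissue without the mutation 2 of 100 did, again with the real one (real 1991, highest other 2059, with K5-Tert tumour 2 in place of the K5-Tert pool). Both shares are under 0.05, but they were not adjusted over the comparisons. In both, another grouping gave more calls than the real one. For K5-Tert against Tert-123 tumours this points to a structure of the samples beside the groups. For Braf tumours against tissue that grouping kept the wild-type and Tert-123C>T pools. It thus shares most of the real grouping and points to no other structure. The groupings by themselves do not exclude chance in either. For all Tert-altered tumours 2 of 100 gave the real 2 or more, a share under 0.05, but the highest other gave 3316, which points to a structure of the samples much larger than the real result.

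K5-Tert differed from Tert-123 tumours in 57 genes higher and 2210 lower, and in Tert by 2.39 on the log2 scale, in direct tests of the difference between the alleles. The gene counts changed with the tumours and the scaling: they were 3 and 14 without K5-Tert tumours 2 and 4, 0 and 3 without 2, 3 and 4, and 675 and 347 after TMM-type rescaling. In 252 groups of values tested for a lone library 15 had one, where chance gives 12.6, about 1 in 20. Tert-123 tumour 7 had a stress score of 7.01 (others 5.16 to 5.71), with Fos at 387.6 TPM, Hspa1a at 161.8 TPM, Atf3 at 160.9 TPM, Fosb at 63.0 TPM and Zfp36 at 104.4 TPM, each above the other 6. K5-Tert tumour 1 had Tle2 at 32.2 TPM, above the other 3. Braf tumour 3 had Arglu1 at 111.8 TPM and Rps14 at 701.9 TPM, above its group, and K5-Tert tumour 3 had Rpsa at 1108 TPM. Lone low values were a macrophage score of 4.74 and Lcn2 at 669.6 TPM in Braf tumour 2, Rps2 at 49.1 TPM in Tert-123 tumour 3, Sftpa1 at 210.1 TPM in Tert-123 tumour 5 and Spp1 at 265.7 TPM in K5-Tert tumour 2.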

How the results depend on the processing

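Chosen only after the data were seen were the tests without Rpph1, with the length trend removed (which also removes each library's mean), without K5-Tert tumours 2 and 4, or 2, 3 and 4, without the tumours of highest Ptprc (Tert-123 tumour 4 and K5-Tert tumour 3), and split by Xist. Of 65 genes named and called in K5-Tert against Braf tumours, 887 of 1369 values under other settings kept direction and side of the threshold, 475 no longer passed and 7 reversed; against Tert-123 tumours 1223 of 1659 kept both, 422 no longer passed and 14 reversed. For Braf tumours against tissue lacking the mutation 3487 of 3575 kept both and 0 reversed. Tert kept its call in K5-Tert tumours under all 5 scalings; without any 1 Braf tumour its exact p against Braf tumours was 0.05714 (35 arrangements), and without any 1 K5-Tert tumour it missed the filter and was not tested by limma. The depth is unknown, so what it limits is not stated. The tests on counts named in advance were not run because the values are scaled to a fixed total and were treated as TPM. Where no reason is given, the cause was not tested.

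Leaving out 1 tumour in turn gave, for K5-Tert against Braf tumours, 17 to 73 genes higher and 381 to 3492 lower. The lower count was 724 without Braf tumour 2, 381 without Braf 3, 723 without Braf 4, 431 without K5-Tert 2, 424 without K5-Tert 4 and 3492 without K5-Tert 1; the higher count was 28, 20, 24 and 26 without Braf tumours 1 to 4 and 73, 17, 23 and 27 without K5-Tert tumours 1 to 4. Against Tert-123 tumours the ranges were 17 to 86 and 528 to 3910. They were 86 and 3910 without K5-Tert 1, 17 and 551 without K5-Tert 2 and 26 and 528 without K5-Tert 4. There were 21 higher without K5-Tert 3 and 1454 lower without Tert-123 3. For Tert-altered tumours they were 0 to 15 and 0 to 1195, with 15 and 1195 without K5-Tert 1, 5 lower without Braf 1, 8 without Tert-123 5, 1 without K5-Tert 3 and 0 without any 1 of the other 11. For Braf tumours against tissue they were 764 to 1818, with 764 lacking the wild-type pool, and 432 to 897, with 1818 and 432 lacking the K5-Tert pool. Tert log2 differences stayed within 2.09 to 2.96 (K5-Tert against Braf), 1.97 to 2.85 (against Tert-123) and 0.04 to 0.24 (Tert-123 against Braf). Calls in Tert-123 against Braf tumours stayed at 0 to 0. List scores past the threshold were also 0 to 0, which says little about stability: with smallest possible p-values of 0.02857 (4 against 4) and 0.00303 (4 against 7), 1 list of 29 alone could not pass the adjustment.

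For K5-Tert against Braf tumours, genes higher and lower were 468 and 373 (TMM-type rescaling), 195 and 470 (quantile normalization), 331 and 399 (length trend and mean removed; 25 and 1358 with the slope alone, 392 and 632 with the mean alone), 106 and 4852 (library weights), 12 and 225 (Xist covariate), 18 and 157 (filter at 50 TPM, fewer genes tested), 28 and 411 (only the groups compared, fewer samples), 3 and 15 (without tumours 2 and 4) and 0 and 2 (without 2, 3 and 4). Higher genes were 135 without Rpph1 and 27 without the tumours of highest Ptprc. For K5-Tert against Tert-123 tumours they were 675 and 347, 233 and 454, and 386 and 433 under the first 3 of these, 94 and 4640 with weights, 23 and 234 with the filter, 35 and 1066 with only the groups compared, 3 and 14, 0 and 3, and 5 and 218 for tumours under 10 TPM of Xist. Higher genes were 193 without Rpph1 and 28 without the tumours of highest Ptprc. The rescalings moved the all-gene median from -0.48 to between -0.38 and 0.10.

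For Tert-123 against Braf tumours there was 1 gene lower with no filter, 1 higher with weights and 1 higher among tumours with Xist of at least 10 TPM. For all Tert-altered tumours 0 were lower with a pseudocount of 0.5, TMM-type rescaling, the Xist covariate, or without tumours 2 and 4, 4 with no filter, and 1 with the filter at 50 TPM or without 2, 3 and 4. Higher and lower were 5 and 4 (quantile), 77 and 3869 (weights), 1 and 1 (without Rpph1) and 2 and 1 (length). For Braf tumours against tissue they were 1811 and 1197 (TMM-type), 439 and 189 (filter at 50 TPM), 1854 and 469 (Braf tumours and wild-type pool only) and 2257 and 1556 (without Rpph1). Higher genes were 3327 with weights and 1850 without K5-Tert tumours 2 and 4, and lower genes were 1423 with no filter, 1432 with quantile normalization and 1528 with the length trend removed.

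Without K5-Tert tumours 2, 3 and 4, which leaves 1 tumour, these log2 fold changes reversed against Braf tumours: Trp63 0.15, Sox9 0.10, Dsc2 0.40, Lama5 0.21, Vegfa 0.11, Rictor 0.025 and Amotl1 0.28. Against Tert-123 tumours Sox9 0.19, Dsc2 0.39, Grhl2 0.11, Esrp1 0.088, Lama5 0.18, Vegfa 0.12, Hmga2 0.053, Etv1 0.11, Trp53inp1 0.13, Ski 0.087, Pmepa1 0.21, Wwc1 0.033 and Amotl1 0.32 did. Insr went to 0.071 against Tert-123 tumours with the length trend removed, and with quantile normalization camera gave the ribosomal protein list of Tert-123 against Braf tumours the other direction without passing, while its median against all genes stayed positive at 0.019.

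List calls were 0 in all 5 comparisons with an estimated correlation and 0 by fry in the 4 between tumours. With the filter at 50 TPM, which tests fewer lists, they were 3 for Tert-123 against Braf, 7 in each of the other 3 between tumours and 8 for Braf tumours against tissue. With quantile normalization they were 2 for Tert-123 against Braf and 11 for K5-Tert against Tert-123 tumours, and in the latter 12 with the length trend removed. With the 6 divisions of the Braf tumours the correlation of the Tert effects was 0.303, 0.268, 0.170, 0.281, 0.303 and 0.259. With a floor of 200 TPM the Tert-123C>T pool had 8 genes higher and 0 lower and the K5-Tert pool 1 and 0.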

Other observations

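Transcripts of the imprinted Dlk1-Dio3 region were followed by level only, as genes chosen after their values were seen. In Braf tumours (n = 4) Dlk1 was at 589 ± 376 TPM, Meg3 at 144.5 ± 67.7 TPM, Rian at 149.5 ± 78.6 TPM and Mirg at 27.1 ± 15.1 TPM, and in the wild-type pool Dlk1 was at 0.106 TPM and Meg3 at 0.305 TPM. In K5-Tert tumours (n = 4) Dlk1 was at 255.1 ± 190 TPM, Meg3 at 15.8 ± 11.02 TPM, Rian at 35.8 ± 15.8 TPM and Mirg at 2.80 ± 0.955 TPM. Dio3, which encodes the deiodinase that inactivates thyroid hormone, stayed at or under 4.37 TPM in every library. The Braf tumour with the lowest Meg3, at 54.9 TPM, still lay above every K5-Tert tumour.

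The keratin genes of basal epithelium, Krt5 and Krt14, were at 29.2 and 61.8 TPM in K5-Tert tumour 1 and at most at 1.21 and 2.05 TPM in the other 3 K5-Tert tumours. The nuclear noncoding RNAs Malat1, Neat1, Firre and Kcnq1ot1 were low together in K5-Tert tumours 2, 3 and 4. Neat1 was at 12.9, 22.3 and 19.6 TPM there and at 60.4 TPM in tumour 1, and Firre at 8.11, 13.2 and 8.01 TPM there and at 35.3 TPM in tumour 1. On the leading principal component, which held 46.3% of the variance, K5-Tert tumours 2, 4 and 3 stood at 79.8, 65.8 and 26.6. Ptprc, the pan-leukocyte gene, was highest in Tert-123 tumour 4 (37.2 TPM) and K5-Tert tumour 3 (35.1 TPM). Immediate-early scores were 8.33 to 8.94 in the pools and 5.10 to 7.01 in the tumours. No explanation was tested for these values.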
